A study of Homo sapiens with 23 samples.

How the data were processed

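Samples were 23 one-colour (Cy3) Agilent human miRNA arrays of MCF-7aro cells and derived lines, 1 array per sample. Per the labels' protocols, 100 ng of total RNA was extracted with Trizol and labelled with pCp-Cy3 for 2 h, and cells were grown in medium with charcoal-stripped serum. The deposited scanner files hold, per the file headers, 1 total gene signal per miRNA as an intensity on a linear scale (negative after background subtraction in places) and a detection flag. Per the submitters' processing notes they were made with Agilent Feature Extraction, and its version is not given in the sources used here. No normalization between arrays is recorded. A deposited table for the whole series holds log2 values. For each probe and array these equalled log2(total gene signal + 10) of the same array, with the added constant between 9.76 and 10.14 and with no scaling or centring, so its scale, centring and direction are known. Its column medians ran from 3.37 to 3.52. It was used as an alternative.

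Each file has 556 rows, with 470 human miRNAs, 64 viral miRNAs and 22 control probes. Control and viral probes stayed out of scaling and tests. Each array was divided by its 75th percentile over the 137 human miRNAs detected on all 23 arrays and multiplied by the geometric mean of these percentiles. Scale factors ran from 1.52 to 2.10 on control arrays and from 0.69 to 1.13 on the others. Values under 2.57 (the median over arrays of the lowest scaled signal among detected miRNAs) were raised to it, and log2 was taken. Human miRNAs detected on every array of at least 1 group (192) were tested, and 250 detected on no array could not be. One limma model was fitted over all 23 arrays with group as the only term (lmFit and eBayes, limma 3.58.1, R 4.3.3, 15 residual and 4.95 prior degrees of freedom), because groups hold 2 or 3 arrays. It gave 18 comparisons and a moderated F test. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All adjusted p-values are from limma.

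Where a miRNA was detected on no array of a group, the fold is a lower bound. It is the bright group's mean over all its arrays against the dim group's mean of, per array, the higher of the lowest scaled signal among detected miRNAs and the miRNA's own signal. These limits are each array's own and can lie under the common floor, so a bound can exceed the fitted fold. Where only some arrays of a group detected the miRNA, the fitted fold is given, which the floor can limit. No fold is given where both groups lacked detection. miR-33, miR-135a, miR-31 and miR-338 were called in such comparisons with control, at most 3 per comparison, and stay in the counts.

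Lists were fixed before the data were examined: 19 families, clusters and functional or check lists, single miRNAs of interest, and the viral probes. The 17 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, in the comparisons with control and with testosterone only, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. Near-identical family members can share probe signal. The rule for named miRNAs took, against control, up to 8 higher and 8 lower called miRNAs with the largest fold change and arrays that do not overlap between the groups, and up to 4 and 4 in other comparisons. It also took up to 4 called members of each list (or the 2 with the highest mean), and the single miRNAs of interest that were called. Non-overlap arises by chance for 10% of miRNAs with 3 arrays against 3, and for 20% with 2 against 3. The tests, the 18 comparisons, the lists and the naming rule were chosen before the data were examined. A contrast of the 4 aromatase inhibitor lines with the testosterone only, T+tamoxifen and LTED lines was chosen after.

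The 3 slides, of 7 or 8 arrays, were entered as a block, and the sign of each call was taken within each slide from single arrays. These are the arrays that gave the calls, so agreement in sign was largely built in. Alternatives covered other scalings, floors and detection filters, the deposited log2 table, slide and replicate number as blocks, fits of the compared groups alone, an intensity trend with robust estimation, and each array left out in turn. The following 2 were added after the data were seen: centring unscaled arrays on their median, and leaving out the G-rich list. Genome coordinates were used only to find gene neighbours, and none are printed. Gene neighbours came from a reference table of GRCh38.p14 genes, matched by name, with 161 of the 192 tested miRNAs matched to exactly 1 gene.

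The method was tested on simulated data with 40 of 192 miRNAs changed, in 20 simulations. For T+letrozole against control it recovered 79.5% of changes of 1 and 97.0% of changes of 2 (log2), with 3.69% false calls. For testosterone only against control it recovered 78.8% and 99.0%, with 3.32% false calls. The simulated values were drawn independently for each miRNA and array on the scaled log2 scale. They held no dim control arrays, scaling step, floor or slide effects. These shares therefore do not cover errors that come from the scaling. Shared controls were simulated 100 times.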

Results

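MicroRNA (miRNA) levels were measured in MCF-7aro cells, the MCF-7 breast cancer line made to overexpress aromatase, the enzyme that turns androgens into oestrogens, and in derived lines kept with hormone or endocrine drugs. The 23 arrays fell into 8 groups. The MCF-7aro control had 3 arrays. Cells kept in testosterone had 2 arrays (testosterone only). Testosterone together with an aromatase inhibitor was represented by T+letrozole, T+anastrozole and T+exemestane, and together with the oestrogen receptor antagonist tamoxifen by T+tamoxifen, with 3 arrays each. Cells resistant to exemestane without testosterone (exemestane only) and long-term oestrogen-deprived cells (LTED) had 3 arrays each. The comparisons were planned with all the drug lines and LTED taken as resistant lines, and MCF-7aro control as their parental line. Differences between these lines and control therefore do not separate drug exposure from resistance. Drug doses and times were not given in the sources used here. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Each array reported 470 human miRNAs, of which 220 were detected on at least 1 array, 137 on all 23, and 192 on every array of at least 1 group. These 192 were tested. miRNA names are those of the array's design without the species prefix, and fold changes are log2 values of scaled signal with the standard error of the limma fit. Adjusted p-values are from that fit.

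The control arrays were dimmer than all others. Total human miRNA signal averaged 31726 ± 7061 (SD, n = 3, arbitrary units) in MCF-7aro control and 51529 ± 6941 (SD, n = 20) on the other arrays, whose lowest value was 39430 (exact permutation test over 1771 splits, two-sided p = 0.00056). Human miRNAs detected per array averaged 157 and 181 (exact permutation test, two-sided p = 0.0011). Both tests take all 23 arrays as exchangeable, though arrays of a group may be technical and the control is 1 group of 8. Their p-values therefore describe these arrays and not the spread between lines. The number of arrays per group limits the precision of every value. Arrays of a group had a median correlation of 0.98 over the tested miRNAs, across miRNAs that are not independent replicates, and arrays of different groups 0.96. No 2 arrays held identical values.

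**Figure D1:**
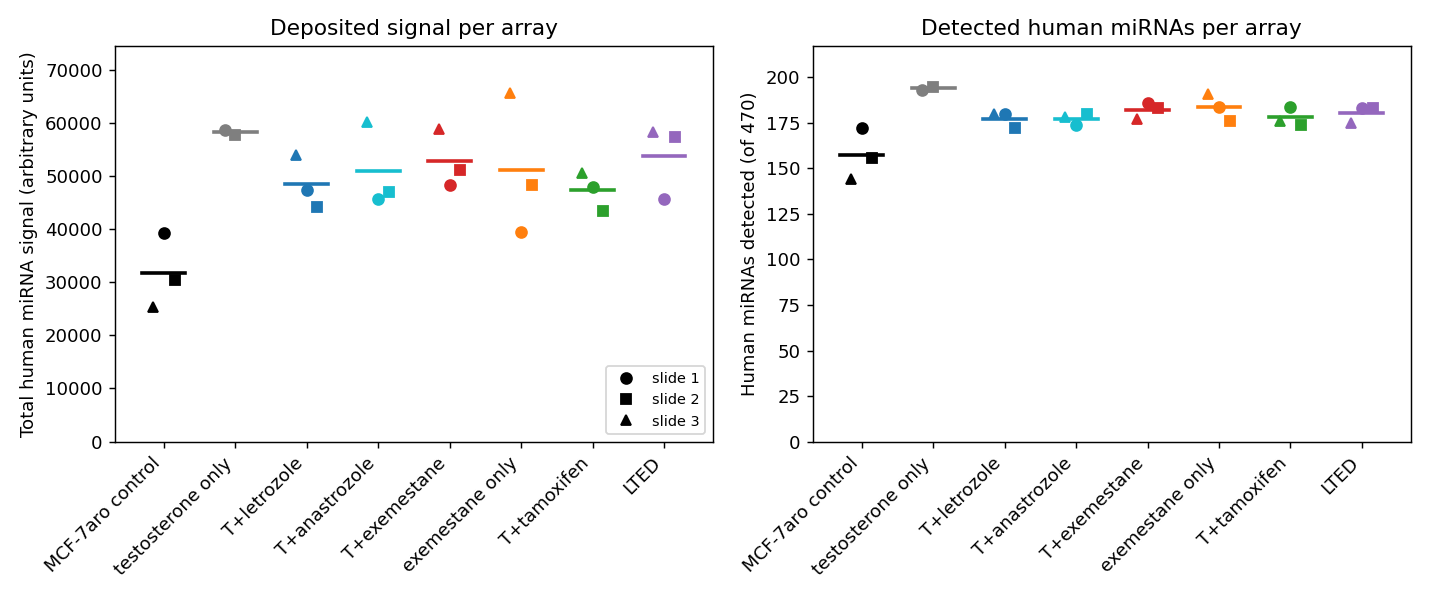
Total deposited signal over human miRNAs (left, arbitrary units) and number of human miRNAs flagged as detected (right) on each of the 23 arrays, by group. Points are arrays, shapes are the 3 slides and lines are group means. The 3 control arrays lie between 25383 and 39334 in total signal, below the lowest other array at 39430.

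Because of this dimness, directions against the control depend on scaling. Without scaling, the median tested miRNA was 0.77 to 1.11 (log2) higher in the 7 lines than in control. With the 75th percentile over all human miRNAs it was 0.11 to 0.25 higher, and with the main scaling it lay between -0.15 and 0.03. All changes below are relative to the main scaling. Without scaling, between 91.1% and 98.2% of the calls in these 7 comparisons were higher, and splits under other scalings are given beside each count where they moved by over 10 percentage points.

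Of the 192 tested miRNAs, 143 differed among the 8 groups (moderated F test). Each slide held arrays of 7 or 8 groups, and testosterone only had no array on slide 3. The first principal component held 40.3% of the variance. Group accounted for 0.95 of its variance and slide for 0.02. With slide as a block, every call of the 7 comparisons with control was made again in the same direction, and further calls were added as stated for each line. The signs on single slides, given below, come from the same arrays that gave the calls. Their agreement is therefore no separate test.

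**Figure D2:**
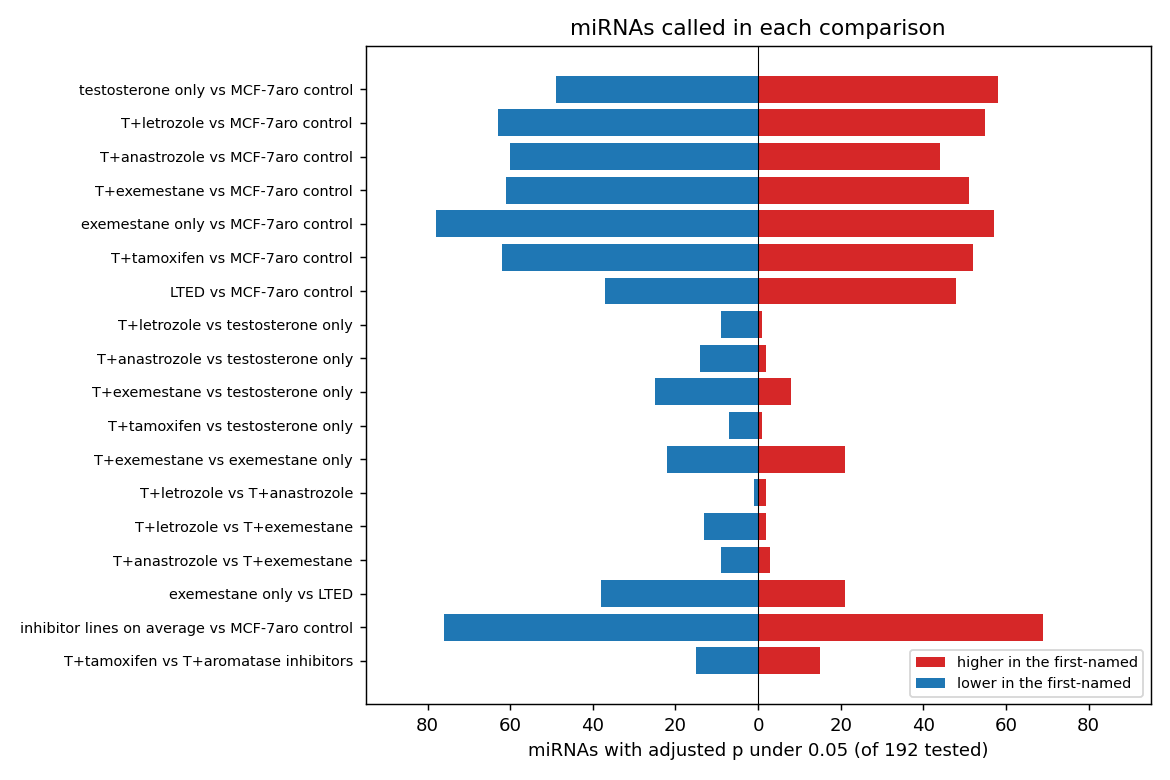
Number of miRNAs with adjusted p under 0.05 in each comparison, higher (red, right) or lower (blue, left) in the first-named group, out of 192 tested. Counts of single lines against MCF-7aro control run from 85 for LTED to 135 for exemestane only, the inhibitor lines on average (the mean of the 5 drug lines and LTED) have 145, and those between treated lines from 3 to 59.

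Testosterone only against MCF-7aro control compares cells on the hormone background of the T+drug lines with the control. It does not isolate an effect of testosterone, since lines kept without it changed alike. Across miRNAs, fold changes of exemestane only and LTED correlated with those of testosterone only at 0.83 and 0.77. Simulation without effects gave 0.44 and 0.45, and all lines share the dim control arrays. In testosterone only, the miRNAs that rose most included miR-489 (3.01 ± 0.47), miR-30e-5p (2.31 ± 0.30), the epithelial miR-200a (2.25 ± 0.26), which represses the transcription factors ZEB1 and ZEB2, and the p53-induced miR-34a (1.83 ± 0.33). miR-489 and miR-30e-5p were detected on 2 of 3 control arrays. miR-34b, detected on no control array, was at least 2.92-fold higher. Among the larger falls were those of miR-181a* (-2.39 ± 0.31) and of miR-222 and miR-221 (-2.27 ± 0.54 and -2.09 ± 0.47), which repress the oestrogen receptor gene ESR1 and the cell-cycle inhibitor CDKN1B. These 2 missed the threshold without scaling, at the same sign (-1.12 and -0.94). In the miR-17-92 cluster and its paralogs, which MYC and E2F drive in proliferating cells, 10 of 14 members rose, 1 fell and 3 did not pass. miR-106b rose by 1.71 ± 0.21 and miR-18a by 1.47 ± 0.23. In the miR-200 family 4 of 6 members rose and 1, miR-200c, fell. Among the former were miR-429 (1.34 ± 0.27) and miR-141 (1.53 ± 0.46), whose call was lost without testosterone only replicate 2 (1.05).

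In all, 58 miRNAs were higher and 49 lower in testosterone only (64 and 63 with slide as a block), and 106 of the 107 had the same sign on each of the 2 slides that hold both groups. The split was 57 and 29 with the percentile over all human miRNAs, 96.9% higher of 129 without scaling, and 38 and 64 after centring unscaled arrays. With replicate 2 of testosterone only left out 64 were called, and with replicate 3 left out 69. By camera with the preset correlation, the miR-17-92 list was higher (adjusted p = 0.013), and the miR-181 family (adjusted p = 0.025) and the G-rich probes (adjusted p = 0.00018) were lower. With an estimated correlation each had an adjusted p of 0.46. The miR-181 call was lost with slide as a block (median -1.16, adjusted p = 0.066). The family's unscaled median was -0.05.

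T+letrozole cells carried testosterone with a non-steroidal aromatase inhibitor. Among the larger falls against control were those of miR-125b (-3.08 ± 0.43), miR-99a (-2.77 ± 0.42) and miR-100 (fitted difference -2.42, limited by the floor, detected on 1 of 3 T+letrozole arrays), which come from let-7 host clusters. The miR-181 family fell in all 5 members, with miR-181a* at -2.74 ± 0.28 (detected on 1 of 3 T+letrozole arrays), miR-181a at -2.59 ± 0.29 and miR-181b at -1.93 ± 0.27. miR-148a fell by 2.42 ± 0.68 on the log2 scale, and its call was lost without scaling (-1.42). miR-200a (1.87 ± 0.23), miR-27b (1.67 ± 0.29), miR-30e-5p (1.67 ± 0.27, detected on 2 of 3 control arrays) and the hypoxia-induced miR-210 (1.21 ± 0.21) rose. miR-34b and miR-660, detected on no control array, were at least 1.98-fold and 1.70-fold higher. miR-21, abundant in breast tumours, was lower (-0.97 ± 0.35), but its sign changed without scaling (0.03) and it was 0 by quantile normalization. Its call was also lost without control replicate 1 (-0.90), T+letrozole replicate 2 (-0.87) or T+letrozole replicate 3 (-0.88).

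By list, 10 of 14 members of the miR-17-92 list rose, 1 fell and 3 did not pass (miR-106b 1.39 ± 0.19, miR-20a 0.87 ± 0.20). All 5 of the miR-10, miR-99, miR-100 and miR-125 list fell, and this list (median -2.42) kept its sign under every scaling. The calls were 55 higher and 63 lower (57 and 72 with slide as a block). Of these 118, 116 had the same sign on each of the 3 slides. The split was 64 and 38 with the percentile over all human miRNAs, 63 and 43 by quantile normalization, and 102 and 7 without scaling. By camera, the miR-17-92 list was higher (adjusted p = 0.0024). The miR-181 family (0.0015), the miR-10, miR-99, miR-100 and miR-125 list (0.0025) and the G-rich probes (0.0015) were lower, by adjusted p. With an estimated correlation the adjusted p was 0.35 for miR-17-92, 0.28 for miR-181 and for the miR-10 list, and 0.70 for the G-rich probes.

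T+anastrozole cells, kept with the other non-steroidal inhibitor, were higher than control in miR-652 (2.34 ± 0.22), miR-27b (1.94 ± 0.29), miR-200a (1.60 ± 0.23) and miR-23b (1.33 ± 0.27). miR-489 rose by 1.44 ± 0.42 (detected on 2 of 3 control arrays) and missed the threshold with control replicate 1 left out (1.06). Falls were measured in miR-181a (-2.57 ± 0.29), miR-181a* (-2.83 ± 0.28, detected on 2 of 3 T+anastrozole arrays), miR-205 (-2.37 ± 0.61), an epithelial miRNA that also represses ZEB1, miR-222 (-1.86 ± 0.48), miR-125b (-1.84 ± 0.43) and miR-100 (-1.72 ± 0.26). Without scaling miR-205 (-1.39), miR-222 (-0.88) and miR-125b (-0.86) kept their sign but missed the threshold. All 4 tested members of the Xq26 cluster rose. Its miR-542-5p, on no control array, was at least 1.64-fold higher.

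The calls were 44 higher and 60 lower (49 and 71 with slide as a block), and 103 of the 104 had the same sign on each slide. The split was 69 and 35 with the percentile over all human miRNAs, 55 and 44 by quantile normalization and 104 and 6 without scaling. By camera, the Xq26 cluster and the miR-17-92 list were higher (adjusted p = 0.047 each). The miR-181 family (0.00078), the miR-10, miR-99, miR-100 and miR-125 list (0.025) and the G-rich probes (0.00028) were lower, by adjusted p. With an estimated correlation each of these 5 lists had an adjusted p of 0.42. In the miR-17-92 list 6 of 14 members rose, 1 fell and 7 did not pass. In the miR-181 family and the miR-10 list all 5 members fell.

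T+exemestane cells carried testosterone with the steroidal inhibitor exemestane. miR-489 rose the most of the named miRNAs (4.02 ± 0.42, detected on 2 of 3 control arrays), and miR-200a (1.99 ± 0.23), miR-652 (1.79 ± 0.22) and miR-195 (1.72 ± 0.31) rose as well, of which the last represses BCL2 and cyclins. miR-653 and miR-338, detected on all 3 T+exemestane arrays and no control array, were at least 2.55-fold and 3.98-fold higher. The largest falls were in miR-205 (-3.65 ± 0.61), miR-125b (-3.46 ± 0.43), miR-99a (-3.32 ± 0.42) and miR-181a (-2.84 ± 0.29). miR-100 was detected on none of the 3 arrays and was at least 6.00-fold lower than in control. All 4 Xq26 members rose. miR-503 and miR-542-5p, on no control array, were at least 2.82-fold and 2.05-fold higher. miR-203 rose by 1.18 ± 0.23.

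The calls were 51 higher and 61 lower (53 and 72 with slide as a block), and 111 of the 112 had the same sign on each slide. The split was 66 and 38 with the percentile over all human miRNAs, 115 and 11 without scaling, and 65 and 50 after centring unscaled arrays. By camera, the miR-10, miR-99, miR-100 and miR-125 list and the miR-181 family were lower (adjusted p = 0.0040 each; 0.43 each with an estimated correlation, as adjusted p), with all 5 members of each past the threshold. The G-rich probes were lower (adjusted p = 0.00036; adjusted p = 0.54 with an estimated correlation). In the miR-17-92 list 4 members rose, 1 fell and 9 did not pass, and the list was not called (adjusted p = 0.18).

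Exemestane only, kept without testosterone, had the most calls. The Xq26 cluster, whose miR-424 and miR-503 repress cell-cycle genes, rose in all 4 tested members. miR-503, miR-542-3p and miR-542-5p, on no control array, were at least 6.83-fold, 4.38-fold and 3.64-fold higher, and miR-424 rose by 2.33 ± 0.38. miR-652 rose by 2.67 ± 0.22 and miR-200a by 1.97 ± 0.23. miR-205 (-3.78 ± 0.61, detected on 2 of 3 exemestane-only arrays), miR-125b (-2.98 ± 0.43), miR-181a (-2.78 ± 0.29), miR-99a (-2.54 ± 0.42) and miR-100 (fitted difference -2.35, limited by the floor, detected on 1 of 3) fell. Of the 14 miR-17-92 members 11 rose, including miR-106b (1.57 ± 0.19), miR-18a (1.35 ± 0.20) and miR-19a (1.29 ± 0.29), 1 fell and 2 did not pass.

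The calls were 57 higher and 78 lower (61 and 78 with slide as a block), and 129 of the 135 had the same sign on each slide. The split was 76 and 53 with the percentile over all human miRNAs, 69 and 59 by quantile normalization and 102 and 10 without scaling. By camera, the miR-17-92 list (adjusted p = 0.0045) and the Xq26 cluster (0.0054) were higher. The miR-181 family (0.0063), the miR-10, miR-99, miR-100 and miR-125 list (0.0066) and the G-rich probes (0.00022) were lower, by adjusted p. With an estimated correlation the adjusted p was 0.34 for the first 4 lists and 0.48 for the G-rich probes.

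T+tamoxifen cells differed from control most in miR-222 (-2.80 ± 0.48) and miR-221 (-2.41 ± 0.42), which kept their calls without scaling, and in miR-205 (-2.43 ± 0.61), which did not (-1.42). miR-489 (2.10 ± 0.42, detected on 2 of 3 control arrays), miR-7 (1.98 ± 0.30), miR-27b (1.93 ± 0.29) and miR-200a (1.37 ± 0.23) rose. In the miR-10, miR-99, miR-100 and miR-125 list 2 of 5 members fell and the list was not called (adjusted p = 0.56). In the miR-17-92 list 11 of 14 members rose and 1 fell. All 5 members of the miR-181 family fell, with miR-181a at -1.60 ± 0.29, a call lost without scaling (-0.59).

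The calls were 52 higher and 62 lower (54 and 68 with slide as a block), and 109 of the 114 had the same sign on each slide. The split was 67 and 41 with the percentile over all human miRNAs and 108 and 6 without scaling. By camera, the miR-17-92 list was higher (adjusted p = 0.0037), and the miR-181 family (0.018) and the G-rich probes (7.2e-05) were lower, by adjusted p. With an estimated correlation each had an adjusted p of 0.60.

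LTED cells, kept without oestrogen or drug, had the fewest calls against control. The p53-induced miR-34a rose by 1.59 ± 0.29, and miR-34b, on no control array, was at least 2.28-fold higher. miR-30e-5p (1.65 ± 0.27, detected on 2 of 3 control arrays), miR-200a (1.45 ± 0.23), miR-210 (1.40 ± 0.21), miR-27b (1.34 ± 0.29) and miR-149 (1.13 ± 0.19) rose. miR-660 and miR-592, on no control array, were at least 1.96-fold and 2.14-fold higher. Among the called miRNAs, the 2 largest falls were in the G-rich probes miR-630 (-1.75 ± 0.25) and miR-622 (-1.44 ± 0.26). miR-181a* fell by 1.19 ± 0.28, a call lost without scaling (-0.26). miR-221 and miR-222 did not pass (-0.48 ± 0.42 and -0.75 ± 0.48).

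The calls were 48 higher and 37 lower (53 and 50 with slide as a block), and 82 of the 85 had the same sign on each slide. The split was 111 and 2 without scaling and 31 and 49 after centring unscaled arrays. With LTED replicate 1 left out 34 were called, and 40 with only these 2 groups in the fit. By camera, the G-rich probes were lower (adjusted p = 2.1e-05; adjusted p = 0.57 with an estimated correlation). No other list was called.

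**Figure D3:**
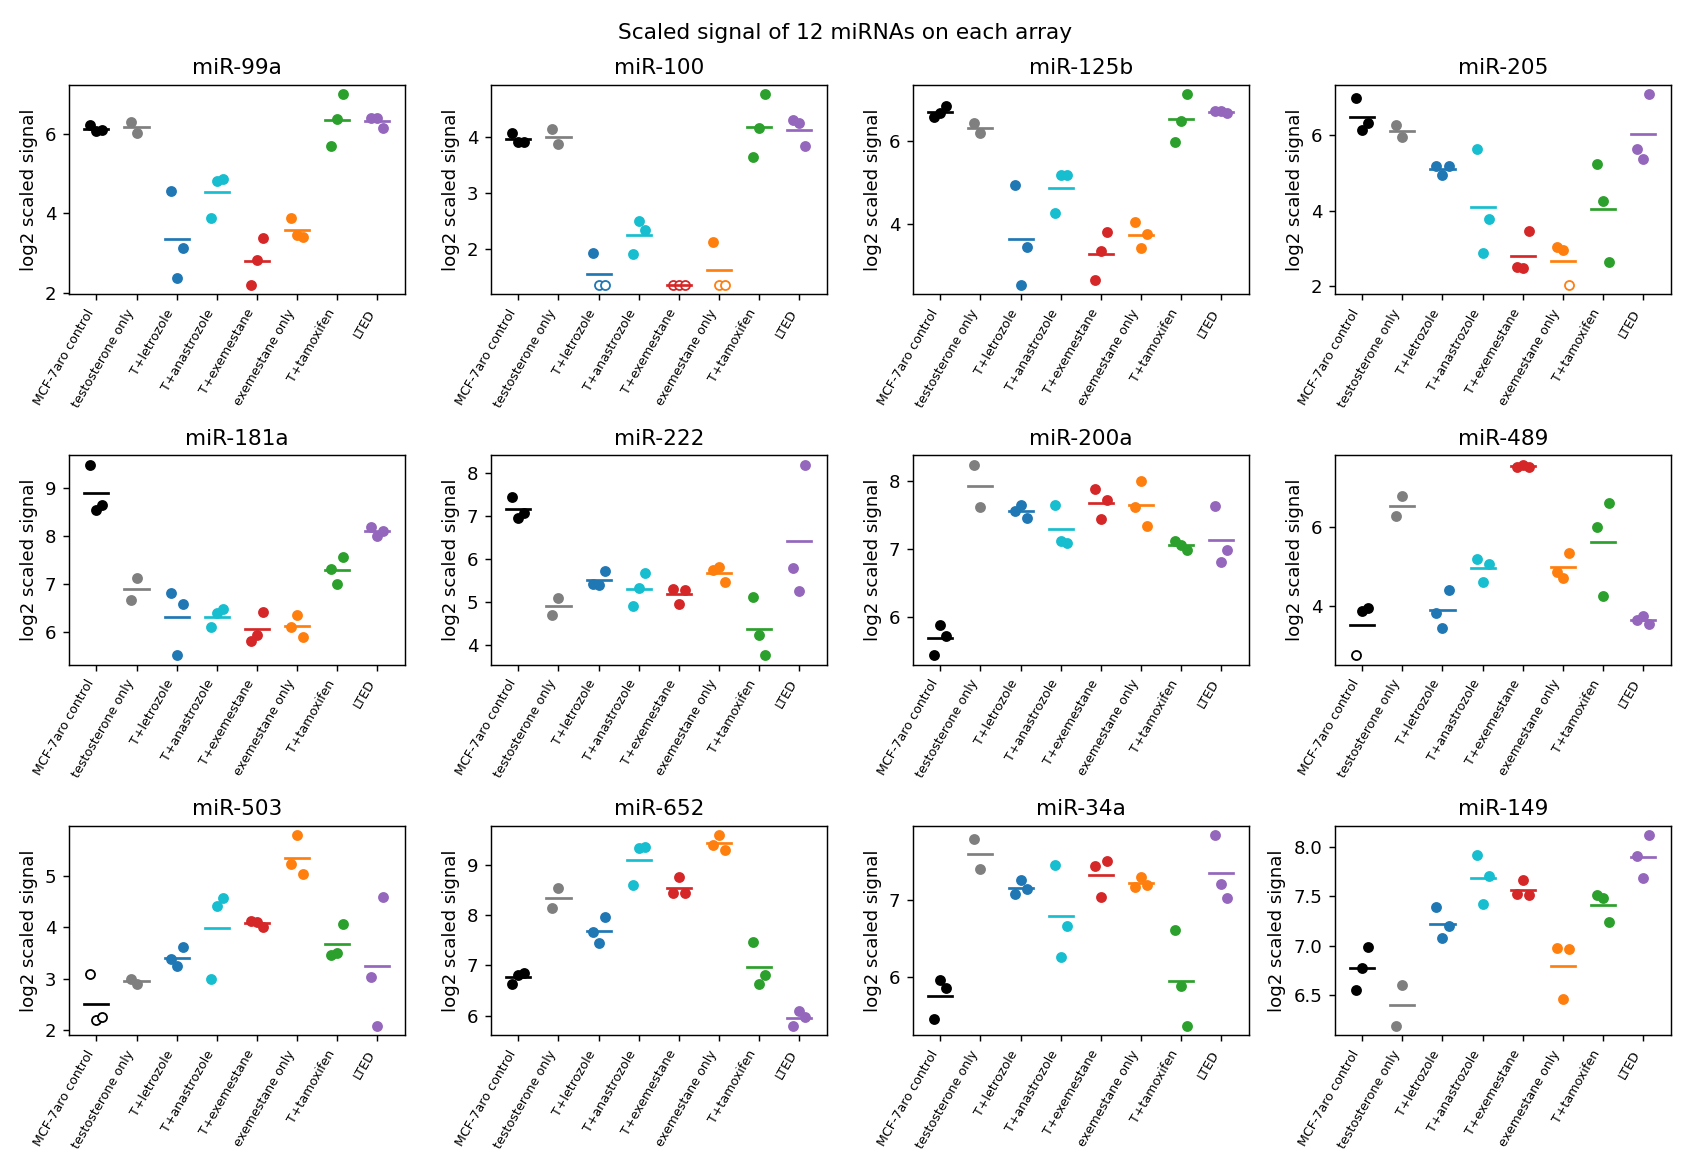
log2 scaled signal of 12 miRNAs on each array, by group. Points are arrays, open circles are arrays where the miRNA was not detected, and lines are group means. miR-99a, miR-100 and miR-125b lie lower on all 12 arrays of the 4 aromatase inhibitor groups than on the 8 arrays of the testosterone only, T+tamoxifen and LTED groups.

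The drugs were next set against the same hormone background. Against testosterone only, T+letrozole was lower in miR-148a (-3.31 ± 0.76), miR-99a (-2.81 ± 0.47), miR-125b (-2.69 ± 0.48) and miR-489 (-2.64 ± 0.47), and higher in miR-149 alone (0.82 ± 0.21). T+anastrozole was lower in miR-100 (-1.76 ± 0.29), miR-141 (-1.78 ± 0.46), miR-99a (-1.64 ± 0.47) and miR-489 (-1.58 ± 0.47), and higher in miR-149 (1.28 ± 0.21). T+exemestane was lower in miR-99a (-3.37 ± 0.47), miR-205 (-3.29 ± 0.68), miR-125b (-3.07 ± 0.48) and miR-148a (-2.99 ± 0.76). In T+exemestane miR-30a-3p and miR-95, on no testosterone-only array, were at least 4.53-fold and 3.19-fold higher. T+tamoxifen was lower in miR-34b (-1.85 ± 0.31, detected on 1 of 3 T+tamoxifen arrays), miR-34a (-1.64 ± 0.33), miR-652 (-1.38 ± 0.25) and miR-29b (-1.26 ± 0.33), and higher in miR-149 (1.01 ± 0.21).

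Several of these calls rested on single arrays or on the scaling. Without testosterone only replicate 2, the calls of miR-148a were lost in T+letrozole (-3.0) and T+exemestane (-2.67), as were those of miR-149 in T+letrozole (0.62), miR-141, miR-99a and miR-489 in T+anastrozole (-1.31, -1.50 and -1.84), and miR-34a, miR-29b and miR-149 in T+tamoxifen (-1.44, -1.05 and 0.81). Without testosterone only replicate 3, the calls of miR-99a (-1.79) and miR-489 (-1.32) in T+anastrozole and miR-29b in T+tamoxifen (-1.48) were lost. miR-149 in T+letrozole was also lost without T+letrozole replicate 1 (0.74) or 3 (0.84), without scaling (0.67) and with the percentile over all human miRNAs (0.93), and in T+tamoxifen without scaling (0.88). In T+anastrozole, miR-99a was lost without T+anastrozole replicate 2 (-1.32), by quantile normalization (-1.26) and after centring (-1.26). There, miR-489 was lost without T+anastrozole replicate 4 (-1.40) or 5 (-1.63) and with 3 other scalings (-1.39, -1.33 and -1.20). miR-29b in T+tamoxifen was lost without T+tamoxifen replicate 1 (-0.99) and after centring (-0.95). With only the groups compared in the fit, no call of T+tamoxifen was left.

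Calls higher and lower were 1 and 9 for T+letrozole, 2 and 14 for T+anastrozole, 8 and 25 for T+exemestane and 1 and 7 for T+tamoxifen. With slide as a block they were 1 and 10, 3 and 17, 9 and 29, and 1 and 14. All of the calls made without the block had the same sign on each of the 2 slides that hold testosterone only. The splits moved with the scaling. T+anastrozole gave 4 and 7 with the percentile over all human miRNAs and by quantile normalization, and 6 and 5 after centring unscaled arrays. T+exemestane gave 10 and 14, 14 and 16, and 28 and 9 with these 3 settings. T+tamoxifen gave 2 and 6, 3 and 7, and 3 and 3, and 0 and 12 without scaling. Each count rests on 2 testosterone-only arrays. With replicate 2 left out the counts were 6, 6, 12 and 2, in the same order, against 10, 16, 33 and 8. With replicate 3 left out T+anastrozole gave 10. T+letrozole gave 6 without its replicate 1, T+exemestane 19 without its replicate 2, and T+tamoxifen 14 without its replicate 1. With only the groups compared in the fit, T+letrozole gave 16 and T+tamoxifen 0 (limma, 35 at an unadjusted p under 0.05 in the fit over all arrays). T+letrozole gave 6 with the percentile over all human miRNAs. T+anastrozole gave 33 without scaling, 26 with log2(scaled signal + 16) and 8 over the miRNAs detected on all arrays.

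By camera against testosterone only, the miR-10, miR-99, miR-100 and miR-125 list was lower in T+letrozole (3 of 5 members, median -2.46, adjusted p = 0.025; adjusted p = 0.73 with an estimated correlation). With slide as a block the G-rich probes were also called higher there (median 0.18 against 0.00 without the block, adjusted p = 0.018; adjusted p = 0.71 with an estimated correlation). In T+tamoxifen the miR-29 family, which represses extracellular matrix genes, and the miR-200 family were lower (adjusted p = 0.0055 and 0.042; adjusted p = 0.44 each with an estimated correlation). In the miR-29 family 2 of 3 members passed over all tested miRNAs and 3 when adjusted over the list alone. In the miR-200 family 0 of 6 passed over all tested miRNAs and 3 when adjusted over the list alone. No list was called in T+anastrozole or T+exemestane, where the smallest adjusted p was 0.057 for the Xq26 cluster and 0.062 for the miR-17-92 list. In T+exemestane 7 of 14 miR-17-92 members were lower than in testosterone only.

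The 3 aromatase inhibitors were compared on the testosterone background. Letrozole and anastrozole are non-steroidal triazoles and exemestane is a steroid. Whether their doses matched is not given. Letrozole and anastrozole differed in 3 of 192 miRNAs: miR-338 was at least 2.05-fold higher in T+letrozole (not detected in T+anastrozole), miR-17-3p was higher (0.84 ± 0.20) and miR-652 lower (-1.41 ± 0.22). The call of miR-17-3p was lost without T+letrozole replicate 2 (0.70) or 3 (0.84), without T+anastrozole replicate 4 (0.72) or 5 (0.81), without scaling (0.86) and with the percentile over all human miRNAs (0.75). The 95% interval of a difference had a median half-width of 0.49 (log2), so the others were not shown to be alike. With slide as a block the counts were again 2 and 1. They were 1 and 1 with the percentile over all human miRNAs and without scaling, and with only these groups in the fit 0 were called (20 at an unadjusted p under 0.05 in the fit over all arrays). The count was 5 without T+letrozole replicate 1.

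Against T+exemestane, T+letrozole was lower in miR-489 (-3.65 ± 0.42), miR-30a-3p (-1.97 ± 0.35, detected on 1 of 3 T+letrozole arrays) and miR-30a-5p (-1.34 ± 0.39). miR-653, on no T+letrozole array, was at least 4.90-fold lower. miR-205 was higher (2.29 ± 0.61), and miR-326, on no T+exemestane array, at least 2.04-fold higher. T+anastrozole was lower than T+exemestane in miR-489 (-2.58 ± 0.42), miR-653 (-2.18 ± 0.26, detected on 1 of 3) and miR-338 (at least 4.78-fold, on no T+anastrozole array), and higher in miR-99a (1.73 ± 0.42) and miR-125b (1.62 ± 0.43). The call of miR-205 was lost without any 1 array of T+letrozole (2.24, 2.36 and 2.25) and without T+exemestane replicate 1 (2.13) or 2 (2.12). That of miR-30a-5p was lost without any 1 array of T+letrozole (-1.41, -1.41 and -1.20) and without T+exemestane replicate 1 (-1.42) or 3 (-1.0). Those of miR-99a and miR-125b were lost without T+anastrozole replicate 4 (1.58 and 1.47) or 5 (1.55 and 1.47) and without T+exemestane replicate 1 (1.43 and 1.31), and that of miR-125b also without T+exemestane replicate 2 (1.67). Counts were 2 higher and 13 lower for T+letrozole (5 and 17 with slide as a block), and 3 and 9 for T+anastrozole (2 and 9). T+letrozole gave 8 calls without its replicate 2, 4 over the miRNAs detected on all arrays and 32 with only the groups compared. T+anastrozole gave 6 and 5 without its replicates 4 and 5, 5 and 7 without T+exemestane replicates 1 and 3, 6 without the detection filter and 4 over the miRNAs detected on all arrays.

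Exemestane with testosterone was compared with exemestane alone. With testosterone miR-489 (2.57 ± 0.42) and miR-338 (1.30 ± 0.20) were higher. miR-653 and miR-30a-3p, on no exemestane-only array, were at least 4.24-fold and 3.97-fold higher. Lower with testosterone were miR-542-3p (-1.80 ± 0.31) and miR-424 (-1.44 ± 0.38) of the Xq26 cluster, miR-101 (-1.60 ± 0.28), which represses EZH2, and miR-29b (-1.38 ± 0.29). Counts were 21 higher and 22 lower (27 and 26 with slide as a block). Left-out arrays moved the total to 22 and 27 (T+exemestane replicates 2 and 3) and 26 (exemestane only replicate 2), and it was 26 without the detection filter.

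Exemestane only and LTED were both grown without added testosterone. With exemestane, miR-652 was higher by 3.48 ± 0.22, miR-542-3p by 2.23 ± 0.31 (detected on 2 of 3 LTED arrays) and miR-503 by 2.12 ± 0.46, a call lost with only these groups in the fit. miR-135a, detected on 2 of 3 exemestane-only arrays and no LTED array, was at least 4.87-fold higher. miR-205 (-3.33 ± 0.61), miR-125b (-2.98 ± 0.43), miR-99a (-2.74 ± 0.42) and miR-100 (fitted difference -2.52, limited by the floor) were lower, with miR-205 on 2 and miR-100 on 1 of the 3 exemestane-only arrays. Counts were 21 higher and 38 lower (26 and 60 with slide as a block). The balance turned with scaling, to 28 and 12 with the percentile over all human miRNAs, 28 and 18 by quantile normalization, 19 and 12 without scaling (31 in all) and 32 and 13 after centring unscaled arrays. The total was 37 without LTED replicate 3 and 21 with only these groups in the fit.

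The 5 drug lines (T+letrozole, T+anastrozole, T+exemestane, exemestane only and T+tamoxifen) and LTED, which carried no drug, were also averaged and set against control in 1 contrast. miR-200a (1.71 ± 0.18) and miR-27b (1.64 ± 0.22) rose, and miR-660 was detected on all 18 arrays of these 6 lines and no control array. miR-33 was called higher, but was detected on 4 of 18 arrays and no control array. miR-181a* (-2.34 ± 0.21, detected on 13 of 18 arrays), miR-181a (-2.19 ± 0.22) and the G-rich probes miR-630 (-2.27 ± 0.19) and miR-622 (-1.71 ± 0.20) fell. Counts were 69 higher and 76 lower (72 and 80 with slide as a block). They were 87 and 52 with the percentile over all human miRNAs and 122 and 7 without scaling.

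T+tamoxifen was set against the mean of the 3 T+aromatase inhibitor lines, an antagonist of the receptor against inhibitors of hormone synthesis. miR-99a (2.80 ± 0.34), miR-125b (2.61 ± 0.35) and miR-100 (fitted difference 2.47, limited by the floor, since miR-100 was detected on 4 of 9 inhibitor arrays and on none of T+exemestane) were higher with tamoxifen, as was miR-7 (1.21 ± 0.24). miR-622 (-0.86 ± 0.21), miR-492 (-0.72 ± 0.20) and miR-339 (-0.52 ± 0.12) were lower. The calls of miR-492 (-0.74) and miR-339 (-0.41) were lost without T+tamoxifen replicate 2, that of miR-492 also without replicate 1 (-0.59), and that of miR-339 by quantile normalization (-0.37). Counts were 15 higher and 15 lower (15 and 17 with slide as a block), and 17 in all without T+tamoxifen replicate 2.

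Calls were shared among the lines. In all 7 lines 15 miRNAs were higher than control, including miR-200a, miR-429, miR-27b, miR-106b, miR-93, miR-29c, miR-301, miR-30e-5p and miR-210. The 15 also hold miR-33, which was detected on no control array and no array of T+letrozole, T+anastrozole, T+exemestane or LTED. In all 7, 26 were lower, of which 10 are on the G-rich list, and others are miR-181a, miR-181a*, miR-99b and miR-200c. Of these, miR-181a and miR-99b were higher than control in LTED without scaling (0.14 and 0.20). Without scaling miR-200c was higher than control in T+anastrozole, T+tamoxifen and LTED. Others of the 26, among them miR-223, miR-654, miR-92, miR-370 and miR-494, were also higher than control without scaling in some lines. That count therefore depends on the scaling. In the 5 drug lines and LTED 17 were higher and 29 lower. Simulated lines without effects, set against the same controls, gave 0 shared calls, and independent lists of these sizes would share 0.067 higher and 0.16 lower. The first value leaves out the effects and the second the shared controls, so neither gives the sharing to be expected of lines that have calls. Fold changes of the 5 drug lines and LTED correlated with those of testosterone only at 0.76 to 0.88 across miRNAs, where simulation without effects gave 0.44 to 0.45. Their covariance was 0.52 to 0.94 against about 0.035 to 0.036 simulated. The 3 controls cannot be split with 2 on each side, so part of the excess may come from the shared controls.

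**Figure D4:**
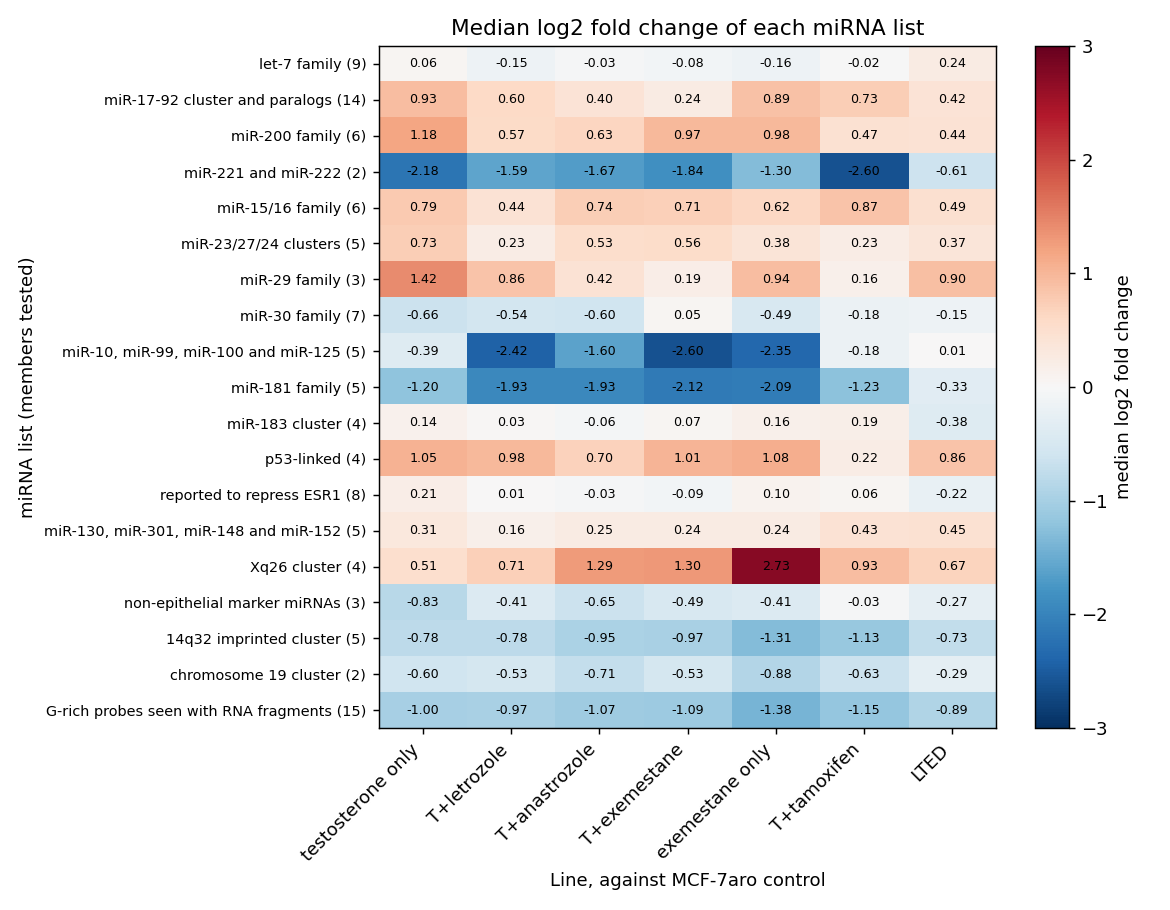
Median log2 fold change against MCF-7aro control of the tested members of each of 19 miRNA lists (rows, number tested in brackets) in the 7 lines (columns). Red is higher and blue lower. The miR-10, miR-99, miR-100 and miR-125 list lies between -2.60 and -1.60 in the 4 aromatase inhibitor lines and between -0.39 and 0.01 in the others, which were above 0 without scaling (0.77 to 0.93).

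The other lists were called in no comparison with control by camera with the preset correlation. Medians against control, in the order testosterone only, T+letrozole, T+anastrozole, T+exemestane, exemestane only, T+tamoxifen and LTED, are given here. The let-7 family, reported as tumour-suppressing, lay between -0.16 and 0.24 (0.85 to 1.21 without scaling), with at most 3 of 9 members past the threshold. The p53-linked list was at 1.05, 0.98, 0.70, 1.01, 1.08, 0.22 and 0.86, with 1 to 3 of 4 members higher and 0 lower. The miR-15/16 family lay between 0.44 and 0.87 with 2 to 4 of 6 higher, and the miR-23/27/24 clusters between 0.23 and 0.73 with 2 to 4 of 5 higher and at most 1 lower. The miR-29 family lay between 0.16 and 1.42 with 1 or 2 of 3 higher and at most 1 lower (miR-29a in T+exemestane and T+tamoxifen, which turned higher without scaling, 0.43 and 0.0087). The miR-200 family lay between 0.44 and 1.18 with 2 to 4 of 6 higher and 1 lower. The lower member in each line was miR-200c (average -0.89 over the 7 lines). On control arrays it was the brightest of the family (log2 12.36 against 5.68 for miR-200a). The miR-30 family moved both ways, between -0.66 and 0.05, all above 0 without scaling. The miR-183 cluster lay between -0.38 and 0.19 with at most 2 of 4 past the threshold (0.52 to 1.23 without scaling). The list reported to repress ESR1 lay between -0.22 and 0.21 with 0 to 4 of 8 members higher and 1 to 4 lower (0.43 to 1.11 without scaling). The miR-130, miR-301, miR-148 and miR-152 list lay between 0.16 and 0.45, with miR-301 higher in every line (1.80 ± 0.30 in testosterone only). miR-221 and miR-222, too few for camera, both fell in every line except LTED (medians -2.60 to -1.30), and in LTED neither passed (median -0.61, 0.31 without scaling).

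Lists that serve as checks were measured as well. Of 19 miRNAs that mark blood, endothelial, fibroblast, muscle, liver or neural cells, 3 were tested. miR-223 was lower in all 7 lines (-1.12 to -0.80), miR-126 passed in testosterone only (-0.83 ± 0.27) and T+anastrozole (-0.65 ± 0.24), and the other tested member in none. Without scaling miR-223 was higher in every line except exemestane only (-0.04), and miR-126 was higher in both lines named (0.32 and 0.33). The list's medians lay between -0.83 and -0.03, and between 0.31 and 0.66 without scaling. In the imprinted 14q32 cluster 3 to 5 of 5 tested members were lower (median -1.31 to -0.73), and 3 of these 5 (miR-134, miR-370 and miR-494) are also on the G-rich list. Its adjusted p was 0.052 or higher, and with slide as a block 0.041 in T+anastrozole, 0.021 in exemestane only, 0.037 in T+tamoxifen and 0.037 in LTED. With that block and an estimated correlation the adjusted p was 0.41, 0.32, 0.54 and 0.61 in these lines. Its unscaled medians lay between -0.23 and 0.37. The placental chromosome 19 cluster had 2 tested members, with medians of -0.88 to -0.29, which were 0.19 to 0.63 without scaling. The G-rich probes, whose Agilent signal is known to move with RNA quality, had 11 to 15 of 15 members lower in each line (medians -1.38 to -0.89), and their unscaled medians lay between -0.31 and 0.16. Of 64 viral miRNA probes, for which no signal was expected, 6 to 12 were detected per array, and 6 to 12 on control arrays.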

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

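The tests for dimmer control arrays and the choice of scaling, and the contrast of the aromatase inhibitor lines with 3 others, were chosen after the results were seen. Cyclic loess and the counts over other splits were chosen before.

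Lines that shared hormone or drug differed from each other by tests of the difference itself (limma, adjusted p under 0.05). Against testosterone only, 10 miRNAs differed in T+letrozole, 16 in T+anastrozole, 33 in T+exemestane and 8 in T+tamoxifen. T+exemestane and exemestane only differed in 43, T+letrozole and T+anastrozole in 3, T+letrozole and T+exemestane in 15, and T+anastrozole and T+exemestane in 12. Exemestane only and LTED differed in 59, and T+tamoxifen and the T+aromatase inhibitor lines in 30. Among the miRNAs called against control, miR-338 was higher in 4 lines and miR-652 in 5, and both were called lower in LTED. Against control, the median tested miRNA in LTED was at 0.82 without scaling and 0.03 with it. Both falls in LTED were therefore not shown apart from the scaling of the dim control arrays. miR-338 was detected on no LTED or control array, so it has no fold there. In exemestane only miR-338 was at least 3.90-fold higher than in LTED (fitted difference 1.69 with LTED arrays at or near the floor; limma, adjusted p = 2.3e-06). For miR-652 the difference was 3.48 ± 0.22 (limma, adjusted p = 2.3e-10). No group had enough arrays to test for outlying arrays, and viral probes were not above the control level.

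In the 3-against-3 comparisons the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls. The highest other count was 0 against 118 for T+letrozole, 0 against 104 for T+anastrozole, 0 against 112 for T+exemestane, 3 against 135 for exemestane only, 1 against 114 for T+tamoxifen and 6 against 85 for LTED, each with control. It was 0 against 43 for T+exemestane with exemestane only, 2 against 3 for T+letrozole with T+anastrozole, 0 against 15 for T+letrozole with T+exemestane, 0 against 12 for T+anastrozole with T+exemestane and 0 against 59 for exemestane only with LTED. Of 100 splits, 1 gave as many as the real 145 for the average of the 5 drug lines and LTED against control (highest other 123, in a split that kept the 3 control arrays together), 1 as many as the real 30 for T+tamoxifen against the T+aromatase inhibitor lines (highest other 24, with the 3 T+tamoxifen arrays together) and 1 as many as the real 143 for any difference among the groups (highest other 23). The splits treat arrays as exchangeable, while the arrays of a group may be technical. They show that arrays of a group resemble each other, and cannot exclude chance differences between cultures.

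Many miRNAs differed between the average of the 5 drug lines and LTED and the control, whose arrays are dimmer. Dimness that is the same for all miRNAs would leave no 2-fold differences after centring unscaled arrays, yet 28 of the 137 miRNAs detected on all arrays differed that much, 14 each way. A distortion that depends on signal is argued against by cyclic loess, which left 95.9% of the 145 calls in the same direction. A difference between the lines stays open, as does a difference in RNA quality between arrays, which was not tested.

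G-rich and viral probes were lower on average in the 5 drug lines and LTED than in control after scaling. The unscaled median difference was -0.084 for the 15 G-rich probes against 1.00 for the other 177 tested miRNAs, and miR-630 was lowest of the 15 at -1.25. The 6 viral probes detected on all arrays had a scaled median difference of -1.05 (-0.04 unscaled), close to the -1.10 of the G-rich probes. A scaled fall of this size thus arose in probes that name no human miRNA. For the G-rich probes, off-target signal that does not follow the miRNA content of the RNA and a fall of the human miRNAs they are named for both stay open. The viral values go with the first, but do not measure the second.

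miR-99a, miR-100 and miR-125b were lower in the 4 aromatase inhibitor lines than in the testosterone only, T+tamoxifen and LTED lines, with all 12 arrays below the other 8. The smallest fall over 4 scalings and the 3 miRNAs was -2.29, so the fall was seen under each scaling. No control array enters this contrast, and the scale factors of its arrays ran from 0.69 to 1.13. A fall of this size could hardly be lost by changing the scaling, so the test excludes little. Cross-hybridisation between the similar probes of miR-99a and miR-100, an effect of the inhibitors and a divergence of the lines during culture stay open and were not tested.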

How the results depend on the processing

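Centring unscaled arrays on their median and leaving out the G-rich list were chosen after the results were seen. All other alternatives were chosen before. The planned normexp background correction was not run, because the values used here hold no mean or background columns. The number of arrays and, for dim miRNAs, signal over the background limit the precision. With slide as a block, the counts of calls stayed within 1.5 times those without it, except T+tamoxifen against testosterone only (15 against 8). Without any array of a comparison in turn, the lowest and highest counts of calls, against the count with all arrays ran as follows. They were 64 to 102 (against 107) for testosterone only vs MCF-7aro control, 89 to 115 (against 118) for T+letrozole vs MCF-7aro control, 76 to 105 (against 104) for T+anastrozole vs MCF-7aro control, 88 to 116 (against 112) for T+exemestane vs MCF-7aro control, 119 to 134 (against 135) for exemestane only vs MCF-7aro control, 95 to 105 (against 114) for T+tamoxifen vs MCF-7aro control, 34 to 101 (against 85) for LTED vs MCF-7aro control, 123 to 155 (against 145) for the 5 drug lines and LTED on average vs MCF-7aro control, 6 to 8 (against 10) for T+letrozole vs testosterone only, 6 to 22 (against 16) for T+anastrozole vs testosterone only, 12 to 31 (against 33) for T+exemestane vs testosterone only, 2 to 14 (against 8) for T+tamoxifen vs testosterone only, 2 to 5 (against 3) for T+letrozole vs T+anastrozole, 8 to 12 (against 15) for T+letrozole vs T+exemestane, 17 to 44 (against 30) for T+tamoxifen vs T+aromatase inhibitors, 5 to 10 (against 12) for T+anastrozole vs T+exemestane, 22 to 36 (against 43) for T+exemestane vs exemestane only, 37 to 70 (against 59) for exemestane only vs LTED, 123 to 148 (against 143) for any difference among the 8 groups. Where 1 testosterone-only array was left out, the other was assumed to vary like the other groups.

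Other settings moved these counts by over 1.5 times, and the cause was not tested. With the percentile over all human miRNAs, T+letrozole against testosterone only gave 6. Without scaling, T+anastrozole against testosterone only gave 33 and exemestane only against LTED 31. With log2(scaled signal + 16), T+anastrozole against testosterone only gave 26. Without the detection filter, T+exemestane against exemestane only gave 26 and T+anastrozole against T+exemestane 6. Over the miRNAs detected on all 23 arrays, which are fewer, T+anastrozole against testosterone only gave 8, and T+letrozole and T+anastrozole against T+exemestane gave 4 each. With the deposited log2 table, T+anastrozole against testosterone only gave 30, T+exemestane against exemestane only 28 and exemestane only against LTED 32. With only the groups compared, which leaves fewer arrays in the fit, LTED against control gave 40, T+letrozole against testosterone only 16, T+tamoxifen against testosterone only 0, T+letrozole against T+anastrozole 0, T+letrozole against T+exemestane 32 and exemestane only against LTED 21. Of lists called by camera with an estimated correlation, 0 were left in any comparison. By fry, which tests whether a list moves 1 way on balance, 12, 9, 11, 11, 13, 8 and 10 lists were called against control (in the order testosterone only, T+letrozole, T+anastrozole, T+exemestane, exemestane only, T+tamoxifen and LTED), and 2, 3, 6 and 2 for T+letrozole, T+anastrozole, T+exemestane and T+tamoxifen against testosterone only.

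Arrays that share a replicate number did not all deviate together (64 pairs, lowest correlation -0.49, median 0.08, 29 over 0.1), so the numbers were not taken to pair them. Outside T+anastrozole, arrays with the same number also share a slide. Arrays on 1 slide deviated together more often (77 pairs, median 0.16, 46 over 0.1, against a median of -0.09 on different slides). With replicate number as a replicate block, T+tamoxifen against testosterone only gave 13 calls and T+letrozole against T+anastrozole 16, and the other counts stayed within 1.5 times.

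Over 533 results for single miRNAs, 10415 alternative values were computed. Of these 9070 kept their direction and side of the threshold, 1177 kept their direction but missed the threshold, and 168 changed sign. None of the 3251 values with an array left out changed sign, and 472 of them missed the threshold. All changes of sign were against control, and the cause was not tested except that the control arrays are dimmer, which values without scaling retain. By quantile normalization miR-200c in T+tamoxifen was 0.18 and miR-494 in LTED 0.16, and miR-21 was 0 in T+letrozole and exemestane only. After centring unscaled arrays miR-378 in testosterone only was -0.29. The other 165 came without scaling and with the deposited log2 table, which is not scaled either, and the pairs of values below are in that order. In testosterone only, the values were 0.59 and 0.57 for miR-320, 0.48 and 0.45 for miR-30d, 0.49 and 0.20 for miR-30e-3p, 0.54 and 0.49 for miR-181d, 0.72 and 0.64 for miR-183, 0.14 and 0.075 for miR-223, 0.32 and 0.21 for miR-126, 0.16 and 0.16 for miR-370, 0.37 and 0.29 for miR-654, 0.49 and 0.49 for miR-494, 0.54 and 0.30 for miR-512-3p, 0.0092 and 0.0090 for miR-638. In T+letrozole, the values were 0.14 and 0.031 for miR-155, 0.48 and 0.48 for miR-193b, 0.028 and 0.028 for miR-21, 0.022 and 0.019 for miR-22, 0.13 and 0.13 for let-7c, 0.40 and 0.40 for let-7b, 0.36 and 0.35 for miR-23a, 0.11 and 0.080 for miR-30c, 0.19 and 0.076 for miR-30e-3p, 0.13 and 0.070 for miR-223, 0.055 and 0.054 for miR-370, 0.15 and 0.082 for miR-134, 0.088 and 0.040 for miR-432, 0.30 and 0.23 for miR-654. In T+anastrozole, the values were 0.14 and 0.13 for miR-22, 0.45 and 0.43 for let-7c, 0.38 and 0.38 for miR-92, 0.13 and 0.13 for miR-200c, 0.17 and 0.060 for miR-30e-3p, 0.37 and 0.27 for miR-30c, 0.041 and 0.023 for miR-223, 0.33 and 0.22 for miR-126, 0.031 and 0.016 for miR-134, 0.16 and 0.12 for miR-654, in the log2 table alone 0.0086 for miR-518c*. In T+exemestane, the values were 0.41 and 0.39 for miR-22, 0.60 and 0.59 for miR-320, 0.46 and 0.44 for let-7c, 0.62 and 0.49 for miR-98, 0.30 and 0.29 for miR-92, 0.43 and 0.40 for miR-29a, 0.28 and 0.26 for miR-30d, 0.15 and 0.082 for miR-223, 0.085 and 0.042 for miR-134, 0.0048 and 0.0064 for miR-432, 0.18 and 0.14 for miR-654. In exemestane only, the values were 0.36 and 0.36 for miR-193b, 0.15 and 0.15 for miR-21, 0.40 and 0.39 for miR-22, 0.42 and 0.41 for miR-320, 0.043 and 0.042 for let-7c, 0.32 and 0.32 for let-7e, 0.34 and 0.34 for let-7b, 0.50 and 0.49 for miR-23a, 0.13 and 0.092 for miR-30c, 0.29 and 0.13 for miR-30e-3p, 0.16 and 0.088 for miR-512-3p, 0.22 and 0.075 for miR-518c*. In T+tamoxifen, the values were 0.26 and 0.26 for miR-193b, 0.44 and 0.43 for miR-320, 0.35 and 0.34 for let-7b, 0.11 and 0.11 for miR-200c, 0.27 and 0.27 for miR-23a, 0.0087 and 0.0085 for miR-29a, 0.17 and 0.16 for miR-30d, 0.047 and 0.038 for miR-181d, 0.038 and 0.019 for miR-223, 0.097 and 0.068 for miR-654, 0.41 and 0.22 for miR-512-3p. In LTED, the values were 0.40 and 0.40 for miR-193b, 0.31 and 0.31 for miR-92, 0.36 and 0.36 for miR-200c, 0.0073 and 0.0058 for miR-30a-3p, 0.20 and 0.19 for miR-99b, 0.14 and 0.14 for miR-181a, 0.51 and 0.46 for miR-183, 0.13 and 0.073 for miR-223, 0.015 and 0.015 for miR-370, 0.033 and 0.015 for miR-134, 0.23 and 0.18 for miR-654, 0.32 and 0.32 for miR-494.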

Other observations

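The mapping to genes that leaves out miRNAs made from several genes was chosen after a first result was seen, and the contrast of the aromatase inhibitor lines with 3 others after the pattern of miR-99a, miR-100 and miR-125b was seen. The test on shared location itself was chosen before.

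The 3 miRNAs that were lower with aromatase inhibitors have relatives that moved less. Across the 4 aromatase inhibitor lines against the testosterone only, T+tamoxifen and LTED lines, miR-99a was lower by -2.71 ± 0.24 (log2). The fitted difference of miR-100, -2.41, is limited by the floor, since it was detected on 5 of the 12 inhibitor arrays and on none of T+exemestane. Their relatives miR-99b (-0.08 ± 0.14) and miR-125a (-0.13 ± 0.13), and let-7a (-0.15 ± 0.14) had smaller differences, none past the threshold. Of these, miR-99b and miR-125a lie beside let-7e on chromosome 19, and not beside miR-99a on chromosome 21. The neighbour of miR-99a, let-7c, was also lower (-0.56 ± 0.10, limma, adjusted p = 0.00046).

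miRNAs from neighbouring genes had similar profiles over the 8 groups. Among 65 pairs of tested miRNAs whose genes lie within 10 kb of each other, the median correlation of group means was 0.74, against 0.03 over other pairs, and 95% of 10000 shuffles lay below 0.23 (one-sided permutation p = 1e-04, the smallest they can give). Over the 61 pairs with different family numbers it was 0.76. The family number is only the number in the name. These pairs still hold members of the same family lists, such as miR-221 with miR-222 and miR-195 with miR-497 (0.99 each). Signal shared between similar probes is therefore not excluded. Hypothesis: shared transcription of neighbouring genes may account for part of the changes, which the median of 0.74 is consistent with. The test does not show which clusters. Of the 65 pairs, 16 had a correlation below 0, among them miR-188 with miR-660 (-0.87), miR-191* with miR-425-3p (-0.85) and miR-17-5p with miR-18a* (-0.75). Of the 192 tested miRNAs, 161 matched exactly 1 gene, and 20 made from several genes were left out.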
